A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

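Chromatin endogenous cleavage with sequencing (ChEC-seq) was used to map Rec8, the kleisin subunit of meiotic cohesin, in budding yeast. In ChEC-seq the protein is fused to micrococcal nuclease, added calcium starts cleavage of DNA next to the protein, and the released fragments are sequenced. The 6 samples were 3 wild-type (WT) and 3 ctf19-9A diploid cultures, each grown from a colony of a different zygote, so the replicates of a genotype were separate cultures. All carried Rec8 fused to MNase and a FLAG tag and lacked NDT80, the gene for the transcription factor that takes cells out of meiotic prophase I. Per the labels' protocols, cells were grown in YP acetate for about 16 h and held in 1% potassium acetate for 4.5 h, and were then given 2 mM CaCl2 for 5 min. The labels give the strain background as X and Y and do not explain these letters.

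The 1 table used here was the authors' own comparison of the 2 genotypes. The submitters' processing notes name FastQC 0.11.9, Bowtie2 2.5.0, deepTools 3.4.3, and DESeq2 without a version, and the genome builds R64 and sacCer3. The role, settings and order of these tools, and the filters on reads and bins, are not given in the sources used here. Each of the 14224 rows of the deposited table is a bin of 20 bp with its chromosome, start and end. Per the file headers, the values are a log2 fold change, a shrunken log2 fold change, a p-value and a false discovery rate, all made by the authors. Every listed bin had a false discovery rate under 0.05, the largest being 0.0500, so bins that did not pass are not analysed here. The rank, p-value and false discovery rate of the last bin imply that 154927 bins entered the adjustment, if it was that of Benjamini and Hochberg. This equals 25.7% of the 603077 bins of that width in the annotated length of the nuclear chromosomes. More may have been tested if some were dropped before the adjustment. Which bins were tested is not given in the sources used here.

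The table holds no value for a single sample. Sequencing depth per sample is therefore unknown, no test across samples was made here, and no SD between replicates can be given. Tests on counts or normalized values had been planned for tables that held them, with the authors' adjusted p under 0.05 as the call otherwise, and that last plan was used. The standard error of each log2 fold change was computed as its size divided by the normal deviate of its two-sided p-value. As a check, the ratio of plain to shrunken log2 fold change, less 1 and divided by the squared standard error, was 10.6 with an SD of 0.036 over all bins, the near-constant value that 1 normal prior would give.

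The direction of the log2 fold change is not stated in the file headers or the labels. Results are therefore given by sign. A ratio of ctf19-9A over WT is the likely reading, on the basis that Ctf19 is a kinetochore protein known to recruit the cohesin loader to centromeres and that the design asks about Rec8 in its mutant. Under that reading a negative value is less Rec8 cleavage in ctf19-9A, and with the sign turned every direction in the text swaps.

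Bins and genes were joined by coordinates on build R64, the assembly of the gene table used here. Each centromere was placed in the gap between the innermost genes of the left and right arms, read from the systematic gene names, and distances were measured to the middle of that gap. The 16 gaps were 630 to 2541 bp long, with a median of 984 bp. The distance of a bin to its centromere is thus uncertain by up to about this length. Chromosome ends were taken as the end of the last gene or the last bin. Intergenic sequence was split by the directions of the flanking genes into convergent, tandem and divergent. Annotations of long terminal repeats and replication origins were not used here, so those planned classes were left out. No listed bin lay on the mitochondrial genome.

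Before the data were examined, the windows, the gene lists, the tests and the naming rule were fixed. The main windows were 10 kb on either side of a centromere, arms of 50 kb or more from a centromere and 20 kb or more from an end, and end regions of 20 kb. The regions named were the bin at or nearest to each centromere, the 10 lowest and 10 highest bins by log2 fold change with at most 1 per 5 kb, the NDT80, REC8 and CTF19 loci, and up to 4 members of each class with the smallest adjusted p. The gene lists were histone, ribosomal protein, glycolytic, early meiotic, and acetate and gluconeogenesis genes. Bins next to each other are correlated. The main tests therefore used the 16 chromosomes as units, in exact two-sided sign-flip permutation tests, whose smallest possible p with all 16 is 3.05e-05. Shares of bins were compared with two-sided Fisher's exact tests, whose p-values treat bins as independent and are too small. Correlations used 100000 permutations. Benjamini-Hochberg adjustment was made within each family of tests. Nearby bins of 1 sign whose starts were at most 500 bp apart were counted as 1 group where groups are given.

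The chromosome-level test was tested on simulated data that kept the real positions of all 14224 bins. Values were drawn independently for each bin, without the correlation between neighbours or the threshold of the real ones. With no planted difference, 5 of 100 runs gave p under 0.05, and planted differences of -0.1, -0.5 and -1.25 were returned as -0.098, -0.50 and -1.25 on average, all with p under 0.05 in each of 20 runs. When the real values were shifted around each chromosome instead, 100 shifts gave differences no lower than -0.65, with p under 0.05 in 8. The test of gene position, for which 100 runs with no planted excess gave p under 0.05 in 7, detected a planted 2-fold excess in 20 of 20 runs. Its positions were also drawn independently, whereas real called bins lie in clusters. The rates of 5 and 7 in 100 runs therefore need not hold for the real bins. Alternatives were another threshold, a minimum fold change, merged bins, other windows, means in place of medians, shrunken values, and chromosomes left out in turn. Work was done in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.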

Results

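Rec8 cleavage was compared between WT and ctf19-9A diploids held in meiotic prophase I, with 3 cultures per genotype. Ctf19 is a kinetochore protein whose phosphorylated N-terminal region binds the cohesin loader, and Rec8 is the meiotic subunit of cohesin, the ring that holds sister chromatids together. The question the design implies is where along the chromosomes Rec8 differs between the genotypes, and whether it differs around centromeres. All fold changes and adjusted p-values of single bins come from the authors' deposited table, which has no value for a single sample, so the depth of each sample is unknown. Signs are those of that table, and the likely reading is ctf19-9A over WT.

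Bins that passed the authors' test fell into 2 sets that lay in different parts of the genome. Negative bins numbered 5576 of 14224 (39.2%), covered 112 kb and had a median log2 fold change of -0.72, with quartiles of -0.88 and -0.60 and a median implied standard error (SE) of 0.18. Positive bins numbered 8648 (60.8%), covered 173 kb and had a median of 0.55, with quartiles of 0.50 and 0.62 and a median SE of 0.17. Negative changes reached further from 0, with a lowest value of -1.55 against a highest positive value of 1.3. They also lay in fewer and longer groups, since merging bins of 1 sign that touched gave 555 negative and 2357 positive regions. With a minimum log2 size of 1, 757 negative and 31 positive bins were left. Bins with a false discovery rate under 0.01 were 3537 negative and 1598 positive, so the majority of positive bins turned into a minority at the stricter threshold.

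Around the centromeres of all 16 chromosomes, Rec8 cleavage changed in the negative direction. Within 10 kb of a centromere lay 4281 negative bins, 76.8% of all negative ones, and within 20 kb lay 5265, or 94.4%. Per chromosome, the median of bins within 10 kb averaged -0.73 (SD 0.13, n = 16 chromosomes), against 0.55 (SD 0.03, n = 16) for bins on the arms. The difference was -1.28 (SD 0.12), negative on 16 of 16 chromosomes, with an exact two-sided sign-flip permutation p of 3.05e-05, the smallest that 16 chromosomes can give. It ran from -1.5 on chromosome XIV to -1.05 on chromosome IX. Of the listed bins within 10 kb, 98.8% were negative, against 13.1% elsewhere, with an odds ratio of 546 by Fisher's exact test with a 95% interval of 413 to 737 that treats bins as independent. Every listed bin passed the authors' threshold, so these medians describe called bins and overstate the average change of all bins.

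**Figure D1:**
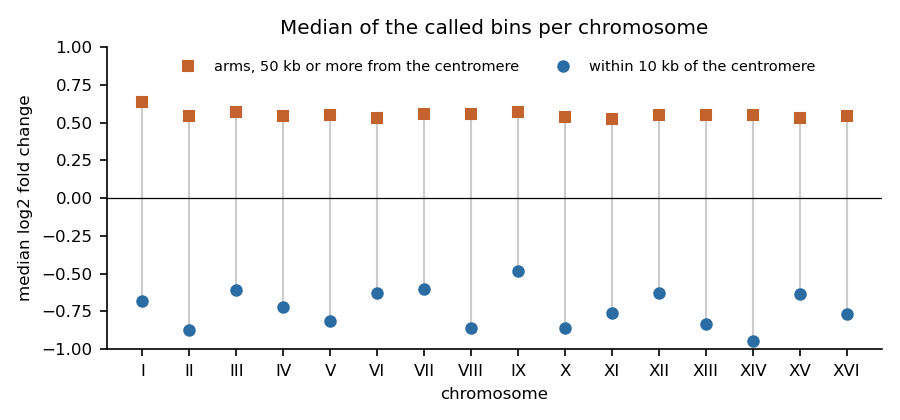
Median log2 fold change of the called 20-bp bins of each chromosome, within 10 kb of the centromere (circles) and on the arms 50 kb or more from it and 20 kb or more from an end (squares). The pericentromeric medians lie between -0.94 and -0.48, all below the arm medians, which lie near 0.55.

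Of the fixed windows, those from 1 to 10 kb from the centromere held the most negative bins, with fewer farther out. Few lay within 2 kb, 13 on the left side and 19 on the right. From 1 to 5 kb, 1693 bins were negative and 0 positive, with a median of -0.76 and a negative median on 15 of 15 chromosomes that had bins there (sign-flip permutation p = 6.1e-05, adjusted p = 0.00012). From 5 to 10 kb, 2583 bins were negative and 0 positive, again with a median of -0.76 and on 16 of 16 chromosomes (permutation p = 3.05e-05, adjusted p = 9.2e-05). Between 10 and 20 kb the median was -0.63 over 984 negative and 5 positive bins, negative on 14 of 15 chromosomes (permutation p = 0.000122, adjusted p = 0.000183). From 20 to 50 kb both signs occurred, 193 negative and 255 positive, and no difference of the chromosome medians from 0 was detected (permutation p = 0.104). With the mean of each chromosome's bins in place of the median, the test passed (permutation p = 0.0199), although the mean over those bins was only 0.0085. At 22 to 24 kb, 93 negative bins with a median of -0.74 lay on the left arms of VII and XII alone and 0 on any right arm, and the lowest bin of VII in the authors' deposited table (-1.13, in ERG4) lay 23.0 kb from the centromere. Beyond 50 kb the median was 0.55, positive on 16 of 16 chromosomes (permutation p = 3.05e-05), with 8336 positive bins and 118 negative ones. Those 118 lay in a single stretch of the right arm of XV (566681 to 594800), with a median of -0.67, in and around BAG7, IDH2, RUP1, SFL1, ARP8 and SUF5.

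**Figure D2:**
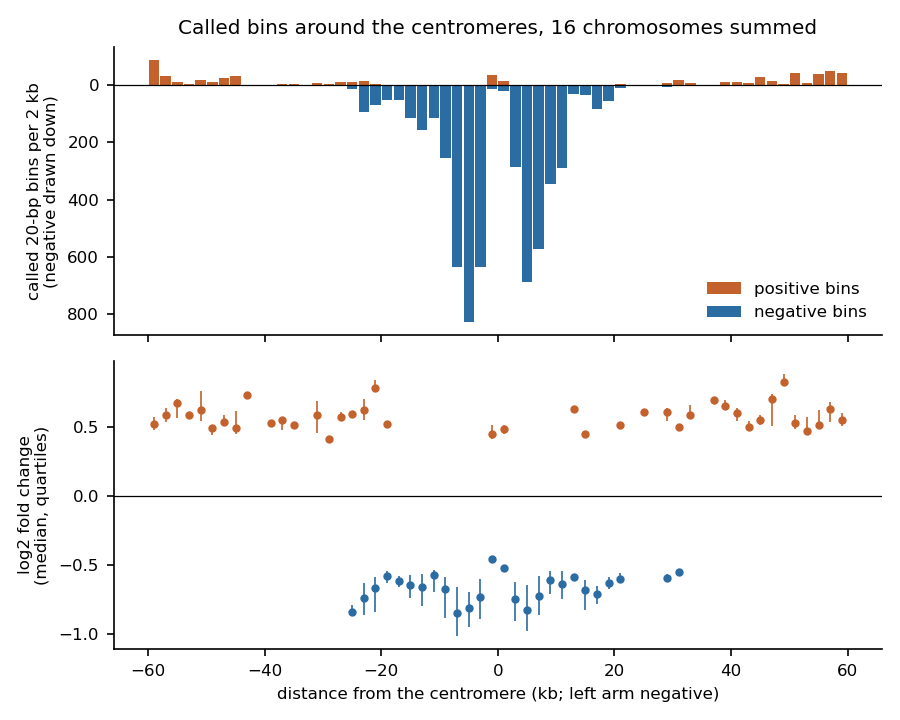
Called 20-bp bins by distance from the centromere in steps of 2 kb, summed over 16 chromosomes. The upper panel counts positive bins upward and negative bins downward, and the lower panel gives the median log2 fold change of each sign with its quartiles; negative bins are most frequent at 2 to 8 kb on the left and 4 to 8 kb on the right, and a small set of positive bins lies at the centromere itself.

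**Figure D3:**
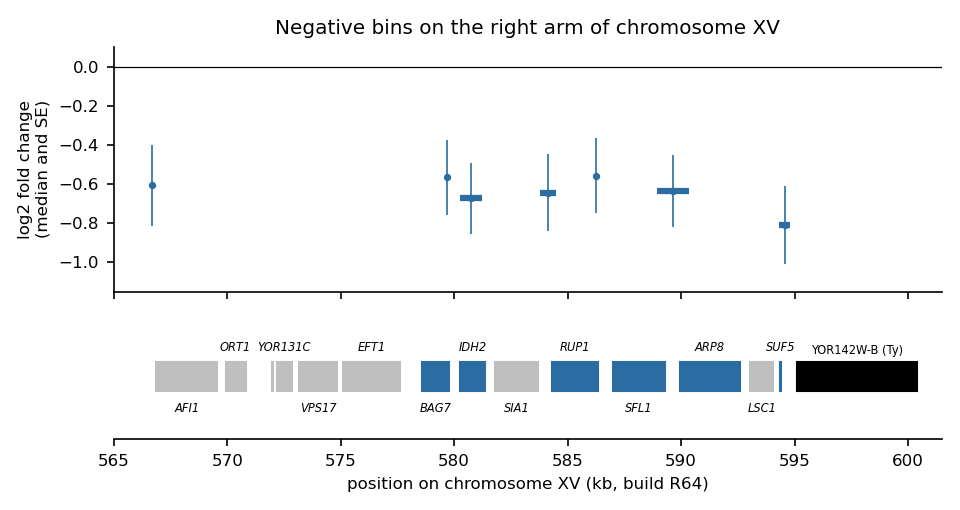
The stretch of chromosome XV (position in kb, build R64) with negative bins far from the centromere. The upper panel gives the median log2 fold change and median implied SE of each of the 7 groups of bins, between -0.81 and -0.56, and the lower panel shows genes (blue with and grey without negative bins) and the Ty open reading frame YOR142W-B (black) beyond the right edge.

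The extent of the negative region differed between chromosomes. Chromosome IV had 537 negative bins within 30 kb of its centromere, chromosome V 515 and chromosome XVI 482, whereas chromosome I had 105 and chromosome III 107, with a median of 346.5 over the 16. The right arms of III and I had few, 13 and 18, next to 94 and 87 on their left arms, whereas VI, also short, had 171 on its right and 79 on its left arm. Within this limit, negative bins reached 24.3 kb from the centromere on the left arm of VII and 29.6 kb on the right arm of XV, but no more than 4.72 kb on the left arm of I. Of the groups with the most negative bins on each chromosome, with starts no more than 500 bp apart, the longest spanned 8.06 kb on the right arm of II, followed by 7.0 kb on the right arm of VII. Of 334 annotated genes centred within 20 kb of a centromere, 158 (47.3%) held a negative bin, 2 held a positive one and 0 held both. This share was 76.7% for the 86 genes at 5 to 10 kb, 74.1% for the 54 at 2 to 5 kb and 17.6% for the 34 nearest ones.

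Genes with the lowest values all lay beside centromeres, 2.46 to 7.97 kb away. In the authors' deposited table the lowest bin of all was in the end of UTP20, a component of the small-subunit processome in ribosome synthesis, on the left arm of chromosome II (235101 to 235120; log2 fold change -1.55, SE 0.19, adjusted p 1.09e-11). The next lowest under this rule in the authors' deposited table lay between the convergent genes LST8 and MRP7 on XIV (621141 to 621160; -1.51, SE 0.20, adjusted p 1.31e-10) and in RAD57, a recombination gene on IV (455881 to 455900; -1.5, SE 0.19, adjusted p 9.5e-11). TRM12 on XIII and PMI40, for phosphomannose isomerase, on V had values of -1.43 each in the authors' deposited table. MRP4, for a mitochondrial ribosomal protein, on VIII followed with -1.38 in the authors' deposited table. The authors' deposited table further gave -1.26 between ULA1 and SNF8 on XVI and in VAB2 on V, -1.22 in MPP10 on X and -1.20 in SYS1 on X, each with 129 to 282 negative bins within 5 kb. MCD1, which encodes the mitotic kleisin that Rec8 replaces in meiosis, lies 4.22 kb from the centromere of IV, held 46 negative bins and had a lowest value of -0.98 in the authors' deposited table, and was picked after its values were seen. The chromosomes whose lowest bin was nearest to 0 in the authors' deposited table had that bin in TFC3 on I (-0.91, SE 0.16), PGS1 on III (-0.83, SE 0.20) and EGH1 on IX (-0.89, SE 0.19).

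At the centromere itself the sign was the opposite. The gap between the innermost genes held 52 positive and 0 negative bins, on 10 of 16 chromosomes, with a median of 0.46, a range of 0.37 to 0.63 and a median SE of 0.14. These 52 were the only positive bins within 10 kb of any centromere. The chromosomes were II, III, IV, V, VIII, IX, XI, XII, XIII and XIV, with the most bins on IV (15), between RMD1 and NTH1, and XIII (13), between YPT7 and CDC5. The authors' deposited table gave 0.44 (SE 0.12, adjusted p 0.0112) for the bin nearest the centromere of IV and 0.42 (SE 0.14, adjusted p 0.0462) for that of XIII. On I, VI, VII, X, XV and XVI the nearest listed bin was negative and outside the gap, in TFC3, SPB4, CUL3, OST1, IZH2 and CIT3, with values from -0.65 to -0.46 in the authors' deposited table. Within 1 kb, the median was 0.45 over 57 bins and was positive on 10 of 11 chromosomes (sign-flip permutation p = 0.00977, adjusted p = 0.0117). The position of the centromere within its gap was not resolved.

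On the arms, positive changes were small and lay between convergent or tandem genes more often than arm sequence does. Positive arm bins were placed in convergent intergenic sequence, a known site of cohesin accumulation in yeast, 6.93 times as often as its share of arm sequence, 25.2% of bins against 3.64%, and higher than that share on 16 of 16 chromosomes (sign-flip permutation p = 3.05e-05, adjusted p = 8.1e-05). Tandem intergenic sequence held 24.6% against 12.6% (16 of 16 chromosomes, same p). Gene bodies held 42.5% against 75.1% (lower on all 16, same p), and divergent intergenic sequence, with promoters on both sides, 7.67% against 8.63% (adjusted p = 0.145). Of positive arm bins inside a gene, 85.0% lay nearer to its 3′ than its 5′ end (above 50 percent on 16 of 16 chromosomes, sign-flip permutation p = 3.05e-05). Which bins could have passed the test is unknown, so these shares describe called bins against all sequence.

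Negative bins near centromeres lay mostly in gene bodies. Gene bodies held 74.6% of negative bins within 20 kb of a centromere against 72.1% of sequence there (11 of 16 chromosomes, sign-flip permutation adjusted p = 0.209). Convergent intergenic sequence held 8.51% against 5.00%, an excess on 13 of 16 chromosomes (adjusted p = 0.0157), and tandem sequence 9.57% against 13.5%, a deficit on 12 of 16 (adjusted p = 0.0192). Inside genes, 56.7% of these bins lay nearer to the 3′ end, above 50 percent on 12 of 16 chromosomes (sign-flip permutation p = 0.00134). Set against each other, convergent intergenic bins made up 8.48% of all negative and 24.9% of all positive bins, by Fisher's exact test with adjusted p = 6.2e-146, and gene bodies 74.5% and 40.2%. Divergent intergenic bins were 7.62% and 8.56% (adjusted p = 0.0485), a difference that turned to 4.91 percentage points the other way with bins within 20 kb of a centromere left out.

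**Figure D4:**
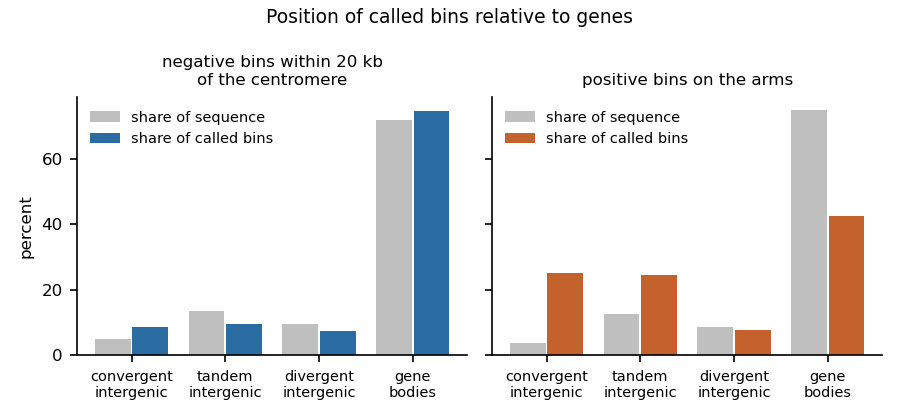
Percent of called bins (coloured) and of sequence (grey) that lies between convergent, tandem or divergent genes or in gene bodies, for negative bins within 20 kb of a centromere (left) and positive bins on the arms (right). Positive arm bins are placed in convergent intergenic sequence at 25.2% against 3.64% of sequence, while gene bodies hold 74.6% of the negative bins against 72.1% of sequence.

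The largest positive values lay at single sites on the arms and at chromosome ends, ranked here with at most 1 bin per 5 kb. The highest in the authors' deposited table was on IV between a tRNA gene, YNCD0020W, and YDR262W (993001 to 993020; 1.3, SE 0.24, adjusted p 1.68e-05), and the next on XIV between SNR19 and POP1 (230801 to 230820; 1.23, SE 0.23, adjusted p 2.1e-05). An inferred Ty open reading frame, YDR261C-D (987534 to 992349), lies just left of the bin on IV, and the distance of the other bins to Ty elements was not examined. The first 100 bp of XII gave 1.22 (81 to 100; SE 0.19, adjusted p 1.03e-07) in the authors' deposited table. Others in the authors' deposited table were 1.11 between YFL064C and COS4 on VI, 1.10 in YAR064W on I, 1.09 between COF1 and LDB18 on XII, and 1.06 between SWH1 and FLO1 on I. The remaining ones in the authors' deposited table had 1.03 each, between KSS1 and BUD9 on VII, between UGX2 and SFA1 on IV, and at the left end of XI. Within 20 kb of an end, 461 bins were positive and 0 negative, with a median of 0.59. Per chromosome they exceeded the arm bins by 0.10 on the log2 scale (SD 0.17, n = 16 chromosomes), on 12 of 16 chromosomes (sign-flip permutation p = 0.00415). The excess was largest on XII (0.58) and I (0.39), which had 8 and 7 end bins. Only called bins enter on both sides, and the authors' threshold ties each value to its standard error. Standard errors were not matched here, so the excess cannot be told apart from an effect of the threshold. Ends carry repeated families such as COS, FLO and Y' genes, whose reads cannot always be placed, and the read filters are not given in the sources used here.

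In the fixed gene classes, most negative bins came from a few genes within 20 kb of a centromere. All 43 bins in histone genes were negative, and the members with bins, HTA2, HTB2 and HHT1, lie within 18.5 kb of the centromere of II, while the other 5 of 8 held no bin, among them HHF1, 17.3 kb from the same centromere. In the authors' deposited table the bin with the smallest adjusted p was -1.23 (SE 0.17, adjusted p 6.1e-10) in HTA2, -0.71 (SE 0.20) in HHT1 and -0.49 (SE 0.15) in HTB2. Of 16 glycolytic genes, TDH2 had 48 negative bins 18 kb from the centromere of X, with -0.83 (SE 0.18, adjusted p 0.000204) in the authors' deposited table, HXK2 and FBA1 had positive bins with 0.59 and 0.45 there, and 13 had none. Among 132 ribosomal protein genes, RPL14A, 7.68 kb from the centromere of XI, held 41 negative bins with -1.02 (SE 0.17, adjusted p 3.8e-07) in the authors' deposited table. A further 7 held positive bins, among them RPL17A (0.74), RPS6A (0.60) and RPS16B (0.59) in the authors' deposited table, and 124 had none, among them RPL14B, 0.889 kb from the centromere of VIII. Of 275 tRNA genes, 29 held positive bins and 1, SUF5, in the far stretch of XV, held negative ones, with 0.71 in SUP53 on III, 24 kb from the centromere, and 0.69 in EMT2 on XV in the authors' deposited table. Fisher's exact tests of negative against positive bins gave adjusted p = 5.9e-18 for histone, 1.29e-12 for glycolytic, 0.000227 for ribosomal protein and 3.8e-12 for tRNA genes. With bins within 20 kb of a centromere left out, no histone bin was left. Glycolytic and ribosomal protein genes then held no negative bin, so their differences could only turn sign and decide nothing (Fisher's exact p = 1 for both). For tRNA genes the difference turned sign on the 3 negative bins in SUF5 (Fisher's exact p = 0.745). With 1 bin per merged region, chosen after seeing the data, the glycolytic call was lost (Fisher's exact p = 0.47) and the ribosomal protein difference turned sign (p = 0.602), each class having its negative bins in a single gene.

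Listed bins were absent from the early meiotic genes (0 of 22), from the acetate and gluconeogenesis genes (0 of 10) and from the rRNA genes (0 of 12). The rDNA locus on XII did hold 23 positive and 0 negative bins, from 460061 to 460640 between rRNA genes, with a median of 0.47 and a median SE of 0.13. The rDNA is a repeated array, so these bins can hold reads of many copies. The early meiotic list holds genes active at the stage sampled, such as SPO11, HOP1 and ZIP1, and the second list those for growth on acetate. A gene without a listed bin may have been untested or not changed, and these cannot be told apart in the table. The edited loci could not check the labels, since no bin lay in NDT80, REC8 or CTF19. The nearest bins in the authors' deposited table were 3377 bp from NDT80 (0.62), 2516 bp from REC8 (-0.59), which lies 14.3 kb from the centromere of XVI, and 6771 bp from CTF19 (0.59).

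Positive bins 50 kb or more from a centromere, here with chromosome ends included, were denser on shorter chromosomes. The density was 195 bins per 100 kb (SD 72.2, n = 3) on I, III and VI and 75 (SD 11.3, n = 3) on VII, XV and IV, the 3 shortest and 3 longest, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 can give. Over all 16 chromosomes density fell with length, with Pearson's r of -0.64 (permutation p = 0.0057, adjusted p = 0.0114) and Spearman's rho of -0.64 (p = 0.0092, adjusted p = 0.0123), and r was -0.73 without I and IV. With bins within 20 kb of an end left out, an alternative chosen after seeing the data, r was -0.59 (permutation p = 0.0174). Negative bins within 30 kb of the centromere were more frequent on longer chromosomes (r = 0.66, permutation p = 0.0049, adjusted p = 0.0114; rho = 0.59, p = 0.0197). Without I and IV that r was 0.48 (permutation p = 0.0797), so the test no longer passed although the direction was kept. Both relations concern numbers of called bins. Which bins were tested on each chromosome is unknown, so more calls need not mean a larger change.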

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

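Alternatives named here as added were chosen after seeing the data: shrunken values, the chromosome XV bins left out, positive bins only at the ends, chromosomes left out for the ends, the ends left out of the density of positive bins, and 1 bin per merged region. Of the settings that leave out no chromosome, 12 counts moved, 5 differences reversed, 2 lost the threshold and 1 came to pass it. The other 46 held. Among them, counts with the mitochondrial genome and rDNA left out changed little, and the rest kept the direction and the side of the threshold. Some of these could not change. No listed bin was mitochondrial, and the chromosome XV bins lie beyond 50 kb, so leaving them out could not alter the profile nearer to the centromere. All 48 settings that leave out 1 chromosome also kept the direction and the side of the threshold. The centromere difference ran from -1.30 to -1.27, and the difference in share of negative bins from 84.9 to 86.9 percentage points. For the former this was fixed in advance, since the difference was negative on 16 of 16 chromosomes. The share differed so widely that leaving out 1 chromosome could hardly move it across the threshold. Only the settings at chromosome ends had much room to change, and there the difference ran from 0.072 to 0.115 (largest sign-flip permutation p = 0.0083). Counts moved by construction, since fewer bins pass or bins are joined. Negative, positive and all bins numbered 3537, 1598 and 5135 at an adjusted p under 0.01, 757, 31 and 788 at an absolute log2 fold change of at least 1, 555, 2357 and 2912 when touching bins were merged, and 3269, 891 and 4160 at an absolute shrunken log2 fold change of at least 0.5. The split between signs therefore depends on the threshold. In the profile at 20 to 50 kb, the sign-flip permutation test gave p = 0.0199 on chromosome means, in place of p = 0.104 on chromosome medians, and the cause was not tested. The mean over all bins there, in which chromosomes with more bins weigh more, was 0.0085 and is not the value tested. With bins within 20 kb of a centromere left out, no histone bin was left. The negative bins left were the 193 at 20 to 50 kb and the 118 on XV. The share among negative less that among positive bins then reversed to 0.138 points for tRNA genes, through 3 bins in SUF5, and 4.91 for divergent intergenic sequence. It also reversed to -0.291 for ribosomal protein and -0.0931 for glycolytic genes, but these then held no negative bin, so no positive value was possible. With 1 bin per merged region the difference in share reversed to -0.255 for ribosomal protein genes and lost the threshold at 0.0953 for glycolytic genes and -1.57 for divergent sequence. Fewer independent bins enter there, but the cause was not tested. No paired analysis was possible because the table used here has no values for single samples. For that reason the replicate block, leaving out each replicate, a filter on low mean signal, another count test or pseudocount, and centring on the arms were not run. Unknown depth limits every value, and bins that did not pass the authors' threshold are not analysed here.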

Other observations

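All tests in this part were chosen after the results were seen. A second stretch of negative bins lay far from any centromere, on the right arm of chromosome XV from 566681 to 594800. Its 118 negative bins in 7 groups, with 0 positive bins among them, lay 240 to 268 kb from the centromere and had a median log2 fold change of -0.67 with quartiles of -0.76 and -0.59. The leftmost group was 1 bin (566681 to 566700, -0.61, SE 0.21), and the next group began at 579641. In the authors' deposited table, genes with negative bins were IDH2, a subunit of mitochondrial isocitrate dehydrogenase (20 bins, lowest -0.76), ARP8, an actin-related subunit of the INO80 chromatin remodeller (19 bins, lowest -0.72), SFL1, a transcriptional repressor (17 bins, lowest -0.88), RUP1 (10 bins, lowest -0.76), BAG7 (4 bins, lowest -0.59) and the tRNA gene SUF5 (3 bins, lowest -0.87). The lowest value of the stretch in the authors' deposited table was -1.0 (594321 to 594340; SE 0.22, adjusted p 0.000297), at its right edge. Outside this stretch and beyond 30 kb from a centromere the table listed 2 negative bins, side by side on VII (527181 to 527220), 30.4 kb from the centromere.

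The right edge of this stretch lay 312 bp from YOR142W-B, a Ty open reading frame (595112 to 600380), while the left edge lay 28431 bp from the nearest of 32 such frames inferred from the gene table. Of nuclear positions, 1.56% lie inside or as near to one, or 3.09% allowing for both edges, against 1 of 32 outer edges of the pericentromeric negative regions. Positions inside a frame are counted, so this is not the share of positions beside a frame, where the edge lies. The frames were found from paired systematic names with a letter suffix. Ty elements named otherwise are missed, so these shares may be too low. Where called bins end also depends on which bins were tested and on the read filters, neither given in the sources used here. A rearrangement at a Ty element relative to the reference, which would place this stretch elsewhere in the strains used, is a candidate explanation that the edge is consistent with, and a test on other data is needed. A decline away from the Ty edge, as beside a centromere, stayed open, since the group medians correlated with distance by r = 0.53 (exact permutation p = 0.178, n = 7 groups; rho = 0.39, p = 0.396) and r = 0.0075 without the 2 groups farthest from the median distance. A copy-number difference of the whole stretch also stayed open. The longest part without a called bin, between the single leftmost bin and the next group, was 13 kb against 1.70 kb in 95 percent of 10000 even draws. This cannot decide, since which bins were tested is unknown. A local effect of the ctf19-9A genotype was not tested.

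Arm calls were almost all of 1 sign. Outside the stretch on XV, 0 negative bins lay 50 kb or more from a centromere, against 8336 positive ones. A common shift of the arm bins, from the authors' scaling or from more Rec8 on the arms, is open, since the count of 0 is the pattern itself and no separate test of it. Separate changes at scattered sites with no shift elsewhere are open too: unchanged bins would give about 308 negative calls there by chance, but only if their p-values were even, and the bins that did not pass are not analysed here. Scaling and a biological gain would both give such a shift, and the values used here cannot tell them apart. A loss near centromeres in a fixed number of reads raises the share of reads elsewhere by construction. The size of that rise is unknown, since neither read counts nor the authors' scaling are given in the sources used here, so it may be far smaller than the shift.

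On each of the 10 chromosomes with positive bins at the centromere, each of these was set against the 20 positive arm bins with the nearest standard error, to ask if they moved like the arms. The chromosome median of these differences per bin averaged -0.025 (SD 0.025, n = 10 chromosomes) and was negative on 9 of 10 (sign-flip permutation p = 0.0078). With the median of the centromere bins less the median of their matched arm bins, the mean was -0.019 (SD 0.029), negative on 7 of 10 and positive on IV, IX and XIII (sign-flip permutation p = 0.0664). Both sets hold only bins that passed the authors' threshold, which ties each value to its standard error, so the same shift as on the arms cannot be told apart from another change at the centromere. No biological explanation of the positive bins was tested.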
